A study of Danio rerio with 15 samples.

How the data were processed

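Small RNA in total RNA of whole zebrafish larvae was measured on 15 one-colour (Cy3) Agilent miRNA arrays. Per the labels' protocols, AB-strain embryos were kept in 0, 0.3, 3 or 30 ppb of the herbicide atrazine from 1 to 72 hours after fertilisation, and RNA was taken from larvae aged 3 days. The labels give 4 arrays each at 0, 0.3 and 3 ppb and 3 arrays at 30 ppb, where replicate 1 was not analysed here. Nothing in the labels says that replicates came from separate clutches or tanks, so p-values measure the spread between these samples, which may be technical.

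Each scanner file holds spot intensity values that the authors extracted with Agilent Feature Extraction 11.0.1.1, per the file headers. The processed intensity is background-subtracted and spatially detrended per the file headers, and it is not scaled between arrays. The same files hold, per the file headers, a total signal per miRNA and other flags per spot for detection and outliers. A deposited table of the authors' processed values is on a log2 scale. Set against the scanner values of detected miRNAs, each of its columns followed the log2 total signal of the same array, with correlations from 0.999873 to 1, minus a constant per array, so its direction is that of the signal. The medians of its columns over all miRNAs lay between -7.06 and -6.50, where most miRNAs were undetected and held the fill-in value of 0.1 before the log. The rule for its constant stays unknown. The authors' deposited list gives a log2 difference and a p-value per miRNA and dose, with the test not given in the sources used here. All 28 deposited log2 differences were within 0.01 of the difference between group means of the authors' processed values. The deposited p-value was within 5% of an unadjusted one-way test over the 4 groups for 27 of the 28 entries.

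Spots flagged as non-uniform or population outliers (2.20% to 3.46% of non-control spots per array) were left out, and the processed intensity was averaged over the other spots of a probe. No spot was saturated. Each array was divided by its 75th percentile over the 463 probes well above background on all 15 arrays, a floor of 0.018 of that percentile was set, and log2 was taken. The brightest of the 1 to 4 probes of a miRNA stood for it. A miRNA was tested if that probe was well above background on at least 3 arrays, which held for 279 of 2068 miRNAs on the array. The number of arrays limits the precision, and between 11.1% and 12.9% of spots per array were well above background.

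Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the miRNAs tested, threshold 0.05), with all 15 arrays in 1 model without a block. The comparisons were each dose against 0 ppb, any dose (moderated F), a linear trend over dose rank, and the differences between doses. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01 and with fry, over zebrafish-named miRNAs, where a list had at least 3 tested members. Detection was compared with Fisher's exact test. The model was tested on simulated data for the same 279 miRNAs, of which 60 were changed. At 30 ppb against 0 ppb it recovered 52.2% of changes of 0.2, 87.2% of changes of 0.4 and 98.0% of changes of 0.8 on the log2 scale. The simulated noise was independent between miRNAs. With fewer changed miRNAs the Benjamini-Hochberg cut-off is stricter, so these shares do not hold for isolated changes, which were not simulated.

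Same-numbered arrays deviated together. The correlations of their deviations from the group means lay between 0.11 and 0.57 for all 21 pairs, with a median of 0.45, against a median of -0.16 for pairs of other numbers and groups, and 14 of 15 arrays correlated best with an array of their own number. In the files each number stood for 1 row of 1 slide, so the replicate number was treated as pairing arrays, and values with it as a block are printed where they changed a call. The 2 slides each held all 4 doses and were each 1 scan. Within a slide, each array column held 1 dose, the same on both slides, so dose and array column cannot be told apart.

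The lists, the comparisons, their tests and the alternatives named below were fixed before the data were examined, while further tests, and alternatives combined with the block, were chosen after. The miRNAs to name were also fixed by rule: all past the threshold at a dose (up to 20), otherwise the 10 with the smallest p-values at each dose, for any dose and for the trend, up to 4 members of each list with the highest mean signal, and the miRNAs of the authors' deposited table. Alternatives were another background correction (normexp with an offset of 50), scaling (quantile, the 75th percentile over all probes, none), summary per miRNA, filters, a floor 4 times lower, blocks for replicate number and slide, array weights, a variance trend, only the groups compared, each array left out, and the authors' processed values. The planned normexp used the median spot signal, because the files used here hold no mean spot signal. Its offset of 50 is added to every signal, which by itself shrinks the log2 differences of dim probes. The 75th percentile over all probes lies among probes not well above background, so it is not a level of detected signal. Coordinates are not printed, since the array annotation names the zebrafish build danRer7 and no genome of that build was used here. Python 3.11.15 and matplotlib 3.10.9 were used for reading files and drawing.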

Results

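The arrays carried probes for 245 zebrafish-named and 1823 human-named miRNAs, and asked which miRNAs of the 3-day-old larva differ after exposure to atrazine through embryogenesis. The summed signal of probes averaged 634200 ± 39490 (SD, n = 4) at 0 ppb, 593700 ± 59420 (SD, n = 4) at 0.3 ppb, 586100 ± 18590 (SD, n = 4) at 3 ppb and 592900 ± 45410 (SD, n = 3) at 30 ppb. Any 2 arrays correlated at 0.995 or above across the tested miRNAs, and no 2 arrays held identical values, with root mean square differences from 0.10 to 0.27 on the log2 scale.

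A larger share of the zebrafish-named than of the human-named miRNAs was above background in the larval RNA. Of the 245 zebrafish-named miRNAs, 154 (62.9%, exact 95% interval 56.5% to 68.9%) were well above background on at least 3 arrays, against 125 of 1823 human-named miRNAs (6.86%, 5.74% to 8.11%; Fisher's exact test, two-sided, p = 4.41e-89). None of 50 miRNAs of the human C19MC and miR-371 clusters, listed beforehand as background, was above background, which allows a share of up to 7.11%. Among the bright zebrafish-named probes were those for the muscle miRNAs dre-miR-206 and dre-miR-133b-3p, dre-miR-124 of neurons and dre-miR-205 of epithelium.

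At 0.3 ppb no miRNA passed the threshold. The 3 smallest p-values belonged to hsa-miR-3907 (log2 difference from 0 ppb -0.29, SE 0.093), hsa-miR-101-3p (-0.20, SE 0.074) and dre-miR-16a (-0.19, SE 0.073), all with an adjusted p of 0.994 in limma. dre-miR-10a-5p, encoded in a Hox cluster, stood at -0.12 (SE 0.054) and dre-miR-101a at -0.12 (SE 0.056). hsa-miR-3613-3p was the one estimate above 0 at an unadjusted p under 0.05, at 0.33 (SE 0.138). In limma 0 of 279 miRNAs passed at an adjusted p of 0.05 and 6 at an unadjusted p under 0.05 (13 with the replicate number as a block), where 13.95 would be expected by chance. The 95% interval lay within 0.5 of 0 on the log2 scale for 272 of the 279.

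At 3 ppb no miRNA passed without a block, and hsa-miR-4687-3p rose with the replicate number as a block. hsa-miR-4687-3p stood at 0.39 with an SE of 0.142 and an adjusted p of 0.895 without the block, and at 0.39 with an SE of 0.049 and an adjusted p of 0.00119 with it. With the block it did not pass with normexp (0.26, SE 0.053) or without scaling (0.25, SE 0.108), nor with the percentile over all probes (0.44, SE 0.162) or without a filter (0.39, SE 0.049, over 2068 miRNAs). hsa-miR-3907 (-0.37, SE 0.093, adjusted p 0.383) and hsa-miR-101-3p (-0.23, SE 0.074, adjusted p 0.895) had the smallest p-values. dre-miR-181a-3p stood at 0.17 (SE 0.059), dre-miR-10a-5p at -0.13 (SE 0.054), and dre-miR-219, a miRNA of oligodendrocytes, at -0.18 (SE 0.077). hsa-miR-4433-5p, at 0.21 (SE 0.088), was above background on 2 of 4 arrays at 0 ppb and on 2 of 4 at 3 ppb. In limma 0 miRNAs passed at an adjusted p of 0.05 and 13 at an unadjusted p under 0.05, of which 6 were lower, and 270 of 279 intervals lay within 0.5 of 0. With the block 28 had an unadjusted p under 0.05, of which 15 were lower. The split moved with the scaling: 21 of 21 were lower without scaling, 23 of 25 with the authors' processed values and 10 of 17 with quantile normalisation. It was 3 of 9 with normexp and 0 of 1 with the percentile over all probes.

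At 30 ppb no miRNA passed without a block, and hsa-miR-4687-3p again rose with it. Its log2 difference was 0.50 (SE 0.153, adjusted p 0.525) without the block and 0.58 (SE 0.054, adjusted p 5.51e-05) with it. The estimates with the smallest p-values were mostly below 0: hsa-miR-3907 (-0.42, SE 0.10, adjusted p 0.257), hsa-miR-101-3p (-0.27, SE 0.080), dre-miR-16a (-0.25, SE 0.079), dre-miR-26a (-0.19, SE 0.073), dre-miR-219 (-0.21, SE 0.083), dre-miR-101a (-0.16, SE 0.061) and dre-miR-10a-5p (-0.16, SE 0.058). In limma 0 miRNAs passed at an adjusted p of 0.05 and 22 at an unadjusted p under 0.05, of which 19 were lower and 3 higher (25 with the block, of which 19 were lower and 6 higher). Of 279 intervals, 267 lay within 0.5 of 0 and all 279 within 1. Without 30 ppb replicate 2 the count was 13, of which 6 were lower. The lower side depends on the scaling. With the percentile over all probes the median of all miRNAs stood at 0.15, 0.05 and 0.26 at 0.3, 3 and 30 ppb, and without scaling at -0.13, -0.14 and -0.11. That percentile lies among probes not well above background, so signs under it are shown as a limit and not as an equal scaling. At 30 ppb 0 of 38 were lower with the percentile over all probes, where dre-miR-10a-5p (0.13), dre-miR-101a (0.13), dre-miR-26a (0.10), dre-miR-219 (0.08), dre-miR-16a (0.05) and hsa-miR-101-3p (0.02) turned above 0 and hsa-miR-3907 (-0.07) did not. Of those at an unadjusted p under 0.05, 15 of 25 were lower with quantile normalisation, 5 of 8 with normexp and 6 of 8 without scaling, but 54 of 57 with the authors' processed values and 37 of 44 with array weights. With normexp, the dim hsa-miR-3907 stood at 0.02, 0.01 and 0.01 at the 3 doses and dre-miR-16a at 0.06, 0.09 and 0.04. The offset of 50 shrinks log2 differences of dim probes. It is added before scaling, which can then lift dim probes at doses with lower unscaled signal. These values above 0 are therefore not read as increases. With normexp hsa-miR-101-3p (-0.01), dre-miR-219 (-0.03) and dre-miR-101a (-0.08) were also nearer to 0 at 30 ppb. So were hsa-miR-101-3p (-0.01), dre-miR-101a (-0.05) and hsa-miR-3613-3p (0.13) at 0.3 ppb. At 3 ppb with normexp dre-miR-219 stood at -0.03, hsa-miR-4433-5p at 0.06 and hsa-miR-101-3p between -0.01 and 0.

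**Figure D1:**
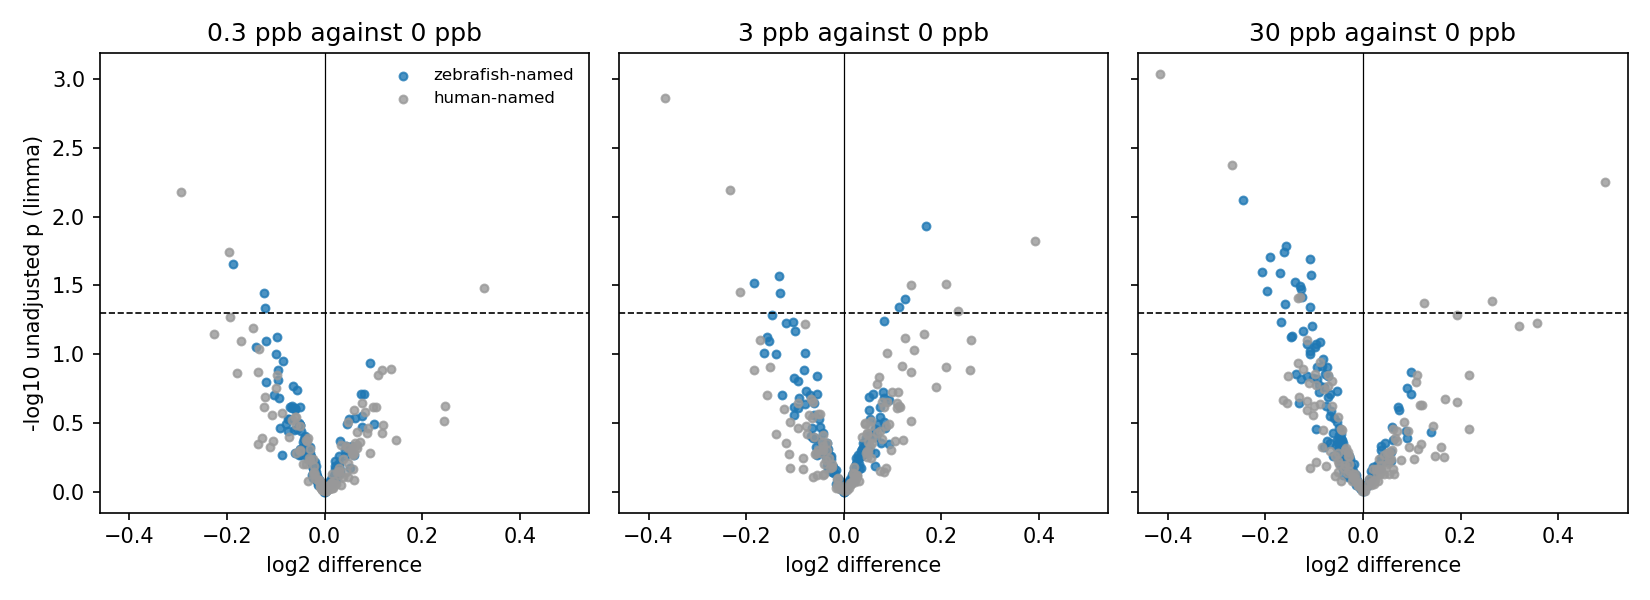
Log2 difference from 0 ppb against -log10 of the unadjusted p from limma for 279 miRNAs at each dose, zebrafish-named in blue and human-named in grey, with the dashed line at an unadjusted p of 0.05. At 30 ppb 22 points lie above the line, 19 of them left of 0 (none of 38 with the percentile over all probes, which shifts all miRNAs), and the point farthest right is hsa-miR-4687-3p at 0.50.

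Over all doses, no miRNA passed the moderated F test, the trend over dose rank or a difference between doses without the block. hsa-miR-3907 had the steepest trend below 0, at -0.14 per dose step (SE 0.033), and hsa-miR-4687-3p the steepest above 0, at 0.18 (SE 0.046), both with an adjusted p of 0.159 in limma. dre-miR-143, dre-miR-26a and dre-miR-219 stood between -0.07 and -0.06 per step, and hsa-miR-1202 at 0.10 (SE 0.036). With the block, hsa-miR-4687-3p rose by 0.20 per step (SE 0.019, adjusted p 1.58e-05), in the F test (adjusted p 0.000144), and between 0.3 and 3 ppb (0.30, SE 0.049, adjusted p 0.0161) and between 0.3 and 30 ppb (0.49, SE 0.054, adjusted p 0.000348). With normexp the blocked estimates were smaller, at 0.33 (SE 0.058) at 30 ppb and 0.12 (SE 0.017) per step, which passed, and at 0.15 (SE 0.053) between 0.3 and 3 ppb and 0.22 (SE 0.058) between 0.3 and 30 ppb, which did not, as in the F test. Between 0.3 and 3 ppb it did not pass either with the percentile over all probes (0.19, SE 0.162), without scaling (0.28, SE 0.108), without a filter (0.30, SE 0.049) or with 4 single arrays left out (0.26 to 0.28), nor between 0.3 and 30 ppb with that percentile (0.66, SE 0.179). Its scaled signal was strictly higher at each higher dose in all 4 replicate numbers. The unscaled signal was lower at 0.3 than at 0 ppb in replicates 1 and 3 and, near 50 at 0 ppb (49.9 ± 11.4, SD, n = 4), is dim. What the human-named probe binds in zebrafish RNA was not analysed here. Dose coincides with array column, so this rise cannot be told apart from a difference between columns. Within slide 1 the blocked trend was 0.23 (SE 0.033, adjusted p 0.0383) and within slide 2 it was 0.18 (SE 0.019, adjusted p 0.00477). At 3 ppb the blocked difference was 0.49 (SE 0.047, adjusted p 0.0414) within slide 1 and did not pass within slide 2 (0.29, SE 0.055, adjusted p 0.348). Counts at an unadjusted p under 0.05 were 5 for the F test, 24 for the trend, and 3, 7 and 7 for 3 minus 0.3, 30 minus 0.3 and 30 minus 3 ppb. With the block they were 15 for the F test, 31 for the trend, 11 each for 3 minus 0.3 and 30 minus 0.3 ppb, and 9 for 30 minus 3 ppb. For the F test and the trend they were 25 and 69 with the authors' processed values, 20 and 46 with array weights, and 2 and 13 with normexp.

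**Figure D2:**
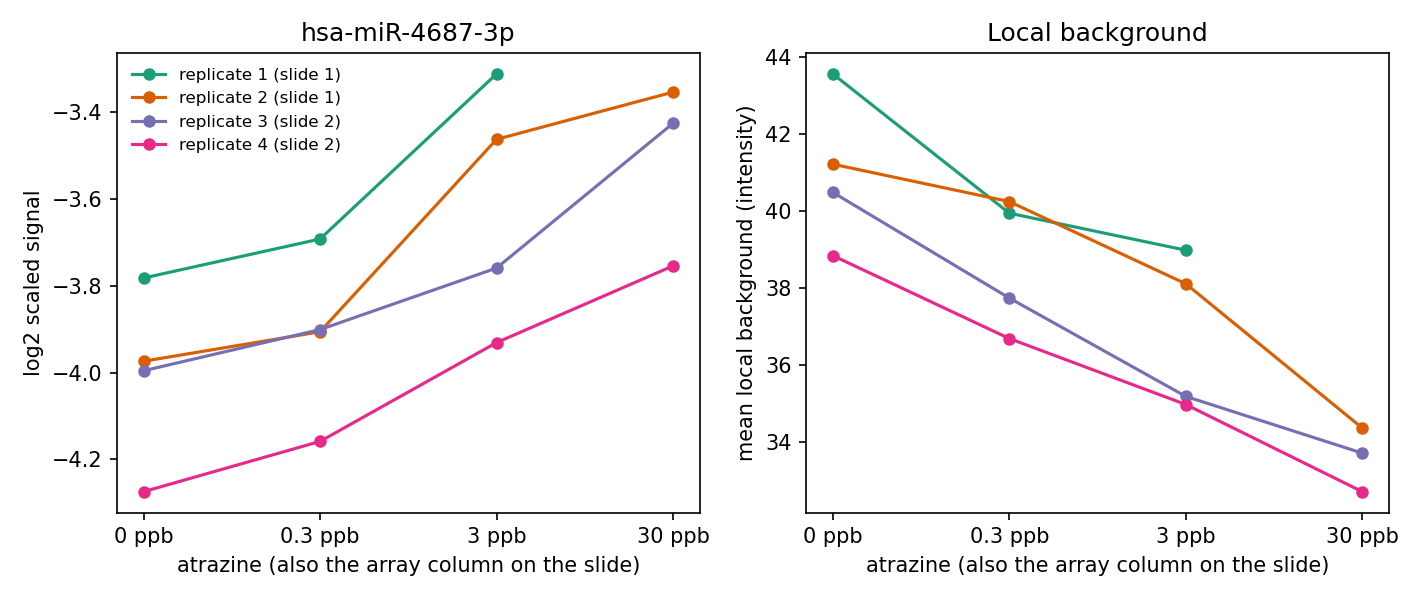
Left, log2 scaled signal of hsa-miR-4687-3p; right, mean local background around the spots; both by atrazine dose, which is also the array column, with one line per replicate number. The scaled signal is higher and the background lower at each higher dose in all 4 replicate numbers.

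Of the miRNA lists fixed beforehand, 14 had enough tested zebrafish-named members, and no list passed at any dose. Lists can share members: the miR-10 members of the Hox cluster list are also in the angiogenesis list, so these lists are not separate evidence. The endothelial and angiogenesis list had the smallest p, at 30 ppb (camera p = 0.00158, and 0.194 with an estimated correlation). All 23 members had estimates below 0 there (median -0.08; dre-miR-143 -0.20 and -0.08 with normexp, dre-miR-10b -0.08, dre-miR-130c -0.05, dre-miR-23b -0.01), all 23 were above 0 with the percentile over all probes, and 17 of 23 were below 0 with normexp. Under the first 2 of these scalings 20 of 23 lay below the median of all miRNAs, and 19 of 23 with normexp. The Hox cluster list had 6 of 7 members below 0 at 30 ppb (median -0.11; dre-miR-10a-5p -0.16, dre-miR-10d-5p -0.11 and -0.07 with normexp), and all 7 above 0 with the percentile over all probes, with 6 of 7 below the median of all miRNAs under both and 5 of 7 with normexp. Adjusted over the list alone with the block, 1 Hox miRNA passed at 0.3 ppb (dre-miR-10a-5p) and 2 at 3 ppb (dre-miR-10a-5p and dre-miR-10c), and without the block 0 passed. The neural list had 9 of 12 members below 0 at 3 ppb and 11 of 12 at 30 ppb (dre-miR-9-3p -0.10, dre-miR-124 -0.03), where all 12 were above 0 with the percentile over all probes and 10 of 12 below the median of all miRNAs under both. Adjusted over the list alone with the block, dre-miR-219 passed at 30 ppb. Without the block, 0 members of any list passed when adjusted over the list alone.

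The hair cell, retina and lens list had all 6 members above 0 at 0.3 ppb and at 3 ppb (median 0.07 at 3 ppb; dre-miR-96 0.06, dre-miR-184 0.08) but 3 of 6 at 30 ppb (median 0.01). At 0.3 and 3 ppb all 6 were below 0 without scaling, with 6 of 6 above the median of all miRNAs under both (5 of 6 at 0.3 ppb and 4 of 6 at 3 ppb with normexp, and 5 of 6 at 3 ppb with the percentile over all probes). The pancreas and endocrine list had all 5 members below 0 at 30 ppb (median -0.12; dre-miR-217 -0.16 and dre-miR-216b -0.14, and -0.09 and -0.08 with normexp), and all 5 above 0 with the percentile over all probes, with 5 of 5 below the median of all miRNAs under each scaling. Of the markers of developmental stage, let-7 and miR-125 had a median of 0.01 at each dose. Without scaling all 13 were below 0. There 9, 8 and 10 of 13 lay above the median of all miRNAs at 0.3, 3 and 30 ppb. For this list camera pointed up, at an unadjusted p under 0.05 at 0.3 and 30 ppb but not at 3 ppb, also with the block. At 0.3 ppb it was among the combinations that shared the smallest adjusted camera p. With an estimated correlation or with fry, the list was not under 0.05 unadjusted at any dose. The medians of miR-430 lay between -0.03 and 0.06, with all 3 members above 0 with the percentile over all probes, where 2 of 3 lay below the median of all miRNAs at 0.3 ppb and 1 of 3 at 3 and at 30 ppb. Muscle (7 members), blood (6), epithelium (9), cartilage and mesenchyme (6), miR-17-92 (16), oncogenic (19) and tumour suppressor (27) lists had medians between -0.05 and 0.02, within the shifts of the scalings. Of these, cartilage and mesenchyme at 30 ppb pointed up with a camera p of 0.0140 (adjusted 0.0652). Its camera p was 0.0272 with an estimated correlation (adjusted 0.691) and 0.0136 with the block (adjusted 0.0637), and its fry p was 0.360. Camera pointed up with a median below 0 for muscle, epithelium and cartilage at 0.3 ppb and for blood, epithelium and miR-430 at 30 ppb, and it pointed down with a median above 0 for muscle at 3 ppb. Mean and median differed in sign for cartilage at 0.3 ppb, muscle at 3 and 30 ppb, and let-7 and miR-125 at 30 ppb. Of 42 list and dose combinations, 0 passed with camera at the preset correlation (smallest adjusted p = 0.0508), 0 with an estimated correlation (adjusted p = 0.691), 0 with fry (adjusted p = 0.286) and 0 with the block (adjusted p = 0.0613), and 13 had an unadjusted camera p under 0.05 (1 with an estimated correlation, 4 with fry, 12 with the block). The liver and gut list had 2 tested members and was not tested.

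**Figure D3:**
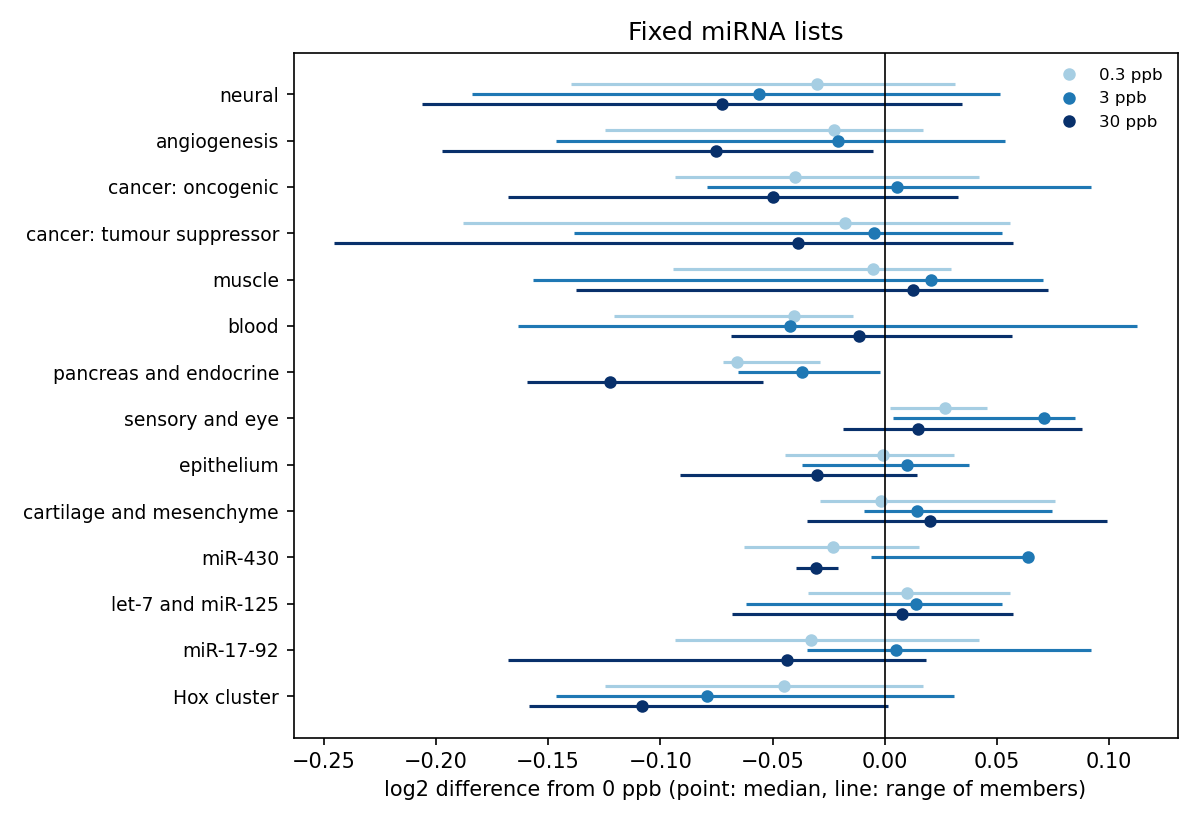
Log2 difference from 0 ppb for each fixed list and dose, with the median of its tested members as a point and the lowest to highest member as a line. The angiogenesis members at 30 ppb all lie below 0, where 20 of 23 lie below the median of all miRNAs (also with the percentile over all probes, which puts all 23 above 0), and no list passed the test.

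The authors' deposited table lists 28 entries of 23 miRNAs (17 zebrafish-named and 6 human-named), all below 0: 1 at 0.3 ppb, 5 at 3 ppb and 22 at 30 ppb. It was chosen on these arrays, so it is not independent evidence of direction. In the authors' processed values the median over 324 miRNAs also stood below 0, at -0.03, -0.05 and -0.08 at 0.3, 3 and 30 ppb. Of its entries, 24 could be tested here and all 24 had estimates below 0, among them dre-miR-26a at -0.19 (SE 0.073), dre-miR-16a at -0.25 (SE 0.079) and dre-miR-18a at -0.11 (SE 0.049) at 30 ppb. With the percentile over all probes 5 of the 24 were below 0, with normexp 20 and with quantile normalisation 23, and 24, 22 and 23 of the 24 lay below the median of all miRNAs under these 3. In limma 0 of the 24 passed at an adjusted p of 0.05, 15 had an unadjusted p under 0.05, and the smallest adjusted p was 0.257. In the authors' deposited table, hsa-miR-126-3p stood at -2.91, -2.92 and -2.98 at 0.3, 3 and 30 ppb and hsa-miR-10b-3p at -4.01 at 30 ppb. The probes of both were not well above background on enough arrays to be tested here, and the scanner software detected hsa-miR-126-3p on 3 of 4 arrays at 0 ppb and hsa-miR-10b-3p on 4 of 4, and neither on any array of the listed doses. dre-miR-126a-3p, an endothelial miR-126 of zebrafish chosen here after its values were seen, was measured on all 15 arrays and stood at -0.04 (95% interval -0.14 to 0.07) at 0.3 ppb, -0.05 (-0.15 to 0.06) at 3 ppb and -0.04 (-0.16 to 0.07) at 30 ppb.

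**Figure D4:**
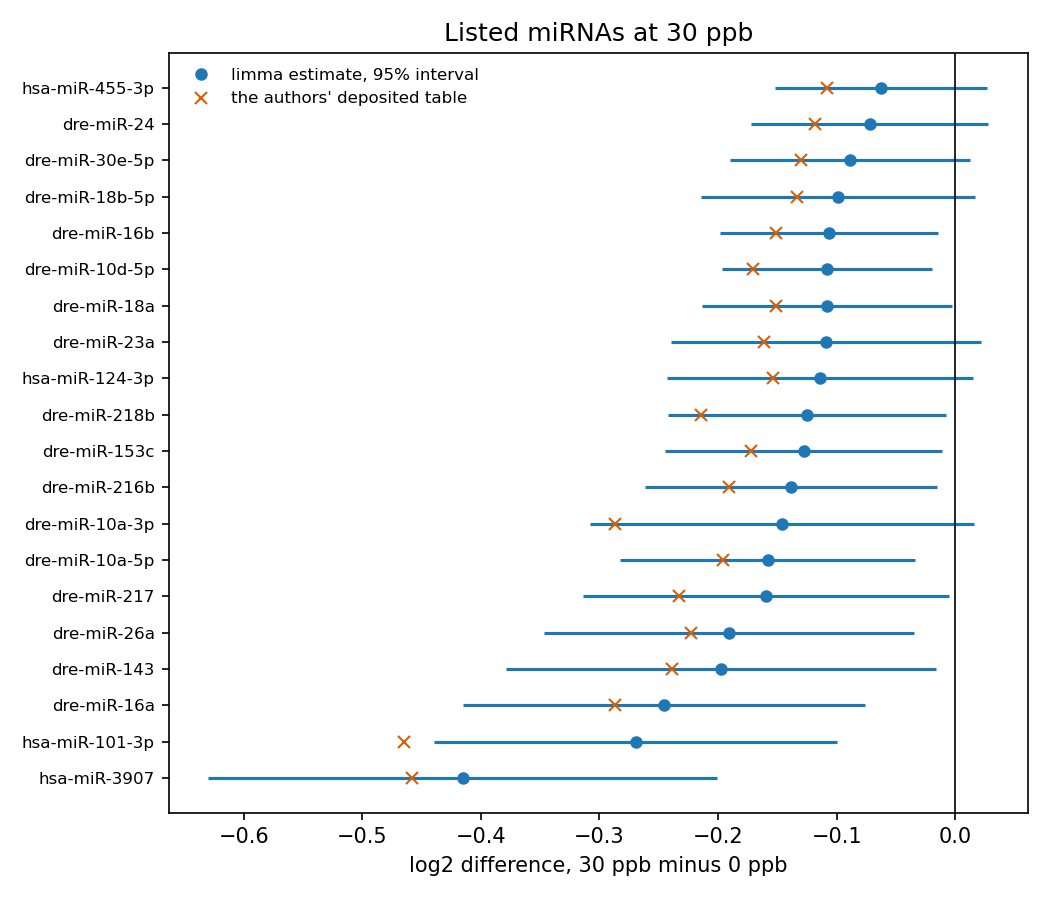
Log2 difference between 30 and 0 ppb for the 20 miRNAs of the authors' deposited table that were tested here, with limma estimates and 95% intervals in blue and the deposited values as crosses. All estimates lie below 0, from -0.06 for hsa-miR-455-3p to -0.42 for hsa-miR-3907, and most turn above 0 with the percentile over all probes, which shifts all miRNAs.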

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

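Of the tests here, those on undetected values, on dre-miR-126a-3p, on array columns, on a gradient across them and on local background were chosen after the results they bear on were seen.

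The 3- to 4-unit decreases of hsa-miR-126-3p and hsa-miR-10b-3p in the authors' deposited table may come from the fill-in value of 0.1 for undetected miRNAs. With undetected values put at the lowest detected total signal of the same array, at most 25.8% of a deposited log2 difference was left. A loss of that size of miR-126 in the larvae is argued against by dre-miR-126a-3p, whose lowest 95% bound over the doses was -0.16. A smaller difference of either human-named miRNA stays open, since neither was well above background.

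hsa-miR-4687-3p was higher at higher doses with the replicate block. The level of local background as its cause stays open. The slope of log2 signal on log2 background was 3.12 (95% interval 2.13 to 4.10) within doses and -2.23 (-2.94 to -1.53) within replicate numbers. The first slope also holds the differences between replicate numbers and the second those between doses and columns, so their opposite signs cannot decide it. With normexp background correction the difference was 0.33 (SE 0.058) against 0.58 (SE 0.054) at 30 ppb and ended the call at 3 ppb (0.26, SE 0.053, against 0.39, SE 0.049). The offset of 50 alone shrinks log2 differences of so dim a probe, so these values cannot decide it either. A smooth gradient running on across the array columns is argued against by the raw signal only. Its slope within arrays along that axis, per distance between columns, was -0.19 (-0.32 to -0.07), opposite in sign to the step of 0.20. The slope on processed signal (-0.12, -0.27 to 0.0372) cannot decide it, since that signal is spatially detrended. Slopes within arrays also cannot show a step between separate arrays. The rule set beforehand for either axis was met by the slope over array height (0.17, 0.03 to 0.31). That slope runs across array rows and so decides nothing about columns. A difference between array columns in handling cannot be told apart from dose, since 0 array columns hold more than 1 dose. Chance was not excluded for the count: 8 of 100 reassignments of doses within replicate numbers gave as many calls (1, highest other 1), 7 besides the real one of which 1 called hsa-miR-4687-3p. A count of 1 could hardly exclude it, since the count leaves out how far past the threshold a call lies. An effect of atrazine stays open and untested against columns.

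At 30 ppb, 19 of 22 miRNAs at an unadjusted p under 0.05 were lower (86.4%, against 19 of 25, 76%, with the replicate block). The scaling between arrays could set part of this share, which was 60% with quantile normalisation, at the bound set for it, 62.5% with normexp and 75% without scaling, but 94.7% with the authors' processed values. The 75% and the 94.7% also come with all miRNAs shifted down, with medians at 30 ppb of -0.11 and -0.08, against -0.03 for the 86.4%. The 0% with the percentile over all probes follows from its shift of all miRNAs. No biological explanation was tested.

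Single arrays stood apart within their group of 4 for 11 of 246 sets of values, where chance gives about 1 in 20 (12.3). The value given is the gap to the nearest array over the range of the group. The percentage of spots well above background was highest on 0 ppb replicate 1 (0.845; 12.9% against 11.5% to 11.7%). On single arrays at 0 ppb, hsa-miR-101-3p was lowest on replicate 4 (0.832) and dre-miR-430c highest on replicate 3 (0.947). At 0.3 ppb, dre-miR-181a-3p was highest on replicate 4 (0.89), dre-miR-10b lowest on replicate 3 (0.909), hsa-miR-455-3p highest on replicate 1 (0.862), and dre-miR-203b-3p (0.839), dre-miR-430b (0.873) and dre-miR-430a (0.836) lowest on replicate 2. At 3 ppb, hsa-miR-324-3p was lowest on replicate 2 (0.861) and dre-miR-153c highest on replicate 1 (0.88).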

How the results depend on the processing

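Combinations of an alternative with the replicate block, and of the block or other values with the authors' list, were chosen after seeing the data. With the replicate block 1 miRNA, hsa-miR-4687-3p, passed at 3 ppb, 30 ppb, in the F test, the trend, and for 3 minus 0.3 and 30 minus 0.3 ppb (adjusted p 0.00119, 5.51e-05, 0.000144, 1.58e-05, 0.0161 and 0.000348), and the block changed no other call over all miRNAs tested (adjusted over the list alone, 3 Hox and 1 neural calls were added, named with the lists). The same miRNA passed at 30 ppb and in the trend with slide as a block (1 each), in the trend with normexp (1), and, with hsa-miR-1268b (named after its values were seen), at 30 ppb and in the trend with the percentile over all probes (2 each; 1 in the F test), a scaling that put the median of all miRNAs at 0.26 at 30 ppb, against -0.03. With the authors' processed values 1 miRNA passed at 30 ppb (hsa-miR-10b-3p, undetected on all 3 arrays there, at -4.01 with the fill-in value of 0.1 and -1.02 with the lowest detected signal in its place) and 1 in the trend (hsa-miR-3907). The cause of the other moves was not tested. No miRNA passed with any array left out without the block (0 to 0 for all comparisons), and none at 0.3 ppb or for 30 minus 3 ppb under any alternative. With the block, hsa-miR-4687-3p passed with each of the 15 arrays left out at 30 ppb (0.56 to 0.61) and at 3 ppb (0.36 to 0.44), while at 3 ppb (0.39, SE 0.049) it did not pass with normexp (0.26, SE 0.053) or no scaling (0.25, SE 0.108), where the difference was smaller, with the percentile over all probes (0.44, SE 0.162), where the SE was larger, or with no filter (0.39, SE 0.049), where 2068 miRNAs were tested (adjusted p 0.0839 to 0.996). With normexp it was also smaller at 30 ppb (0.33, SE 0.058) and in the trend (0.12, SE 0.017), and passed. Its call for 3 minus 0.3 ppb was lost under the same 4 alternatives (0.563 to 0.995) and without replicate 1 or 2 of 0.3 or of 3 ppb (0.0866 to 0.116), that for 30 minus 0.3 ppb with normexp (0.600) and the percentile over all probes (0.0646), and that in the F test with normexp (0.0702). Of 200 combinations of comparison and alternative with the block, 10 passed another miRNA: hsa-miR-3907 (at 3 ppb and in the F test without scaling, at 3 ppb without 3 ppb replicate 2, in the trend with the authors' values or without 0.3 ppb replicate 2), dre-miR-219 at 30 ppb, dre-miR-16b and hsa-miR-1268b in the trend, hsa-miR-1202 in the trend and for 30 minus 0.3 ppb, and there hsa-miR-3676-5p (named after its values were seen). Of 6918 alternative values of 231 miRNA and dose combinations, 544 had the opposite sign, in 196 of the 231 combinations under at least 1 alternative, and none of these passed. Without the percentile over all probes and no scaling, which shift all miRNAs, it was 356 of 6456 values, in 113 combinations. No list passed under the alternatives run on lists, 0 of the 24 entries of the authors' list tested here passed with the block, a plain test, quantile normalisation or the authors' values (the calls of hsa-miR-3907 at 3 ppb and hsa-miR-10b-3p named above are of entries too, the latter not among the 24), and the odds ratio of zebrafish-named against human-named detection was 22.9, and 22.6 with all 15 arrays required. Signals near background, such as hsa-miR-3907 near 20.8 at 0 ppb, limit how small a difference can be seen.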

Other observations

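The exact tests of array measures and of hsa-miR-4687-3p, and the simulation of shared controls, were chosen after results were seen. Doses shared the same 4 control arrays, and their log2 differences correlated across miRNAs, which are not independent replicates. The correlation was 0.68 between 3 and 30 ppb, against 0.46 with simulated unchanged groups, 0.22 with split controls, and a covariance of 0.00543 against a simulated 0.00343. It was 0.59 between 0.3 and 3 ppb (0.49 simulated, 0.06 with split controls, covariance 0.00346 against 0.00337) and 0.51 between 0.3 and 30 ppb (0.46, 0.04, 0.00331 against 0.00344). The simulation took its spread from the model without the block, so the values expected with paired arrays and no change are not known from it.

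Other splits of the same arrays gave as many miRNAs at an unadjusted p under 0.05 in each comparison, so chance was not excluded for any of these counts. At 0.3 ppb 29 of 35 splits gave as many (real 6, highest other 68), at 3 ppb 6 of 35 (real 13, highest other 38) and at 30 ppb 7 of 35 (real 22, highest other 36). For the F test it was 88 of 100 (real 5, highest other 51), for the trend 14 of 100 (real 24, highest other 71), for 3 minus 0.3 ppb 34 of 35 (real 3, highest other 37), for 30 minus 0.3 ppb 31 of 35 (real 7, highest other 65) and for 30 minus 3 ppb 14 of 35 (real 7, highest other 26). Splits that call several times the real count point to a structure of the arrays. Among the 8 splits that part all pairs at 30 ppb, 1 gave as many, the real one, with a highest other of 6, and at 3 ppb also 1, with a highest other of 8, while the splits with higher counts there mixed same-numbered arrays within a group. Pairing does not account for all of it: among such splits the highest other was 16 at 0.3 ppb, 19 for 3 minus 0.3 ppb, 10 for 30 minus 0.3 ppb and 16 for 30 minus 3 ppb, and 5, 7, 4 and 2 of 8 gave as many, counting the real one. With 8 such splits the smallest possible share is 1 of 8, so they could not exclude chance in any comparison. For the counts of the F test and the trend, splits that part pairs were not run. Leaving out 1 array moved the count at 30 ppb to between 12 and 28, with 12 without 0 ppb replicate 1 or replicate 3, 13 without 30 ppb replicate 2 (6 lower) and 13 without replicate 4 (12 lower). At 3 ppb it was 6 without 3 ppb replicate 2, 7 without 3 ppb replicate 4 and 8 without 0 ppb replicate 3, and at 0.3 ppb 10 without 0.3 ppb replicate 1. The F test gave 8 without replicate 3 of 3 or 30 ppb, 9 without 3 ppb replicate 1 or 0.3 ppb replicate 3 or 4, 10 without 0.3 ppb replicate 1 or 0 ppb replicate 2, and 11 without 0.3 ppb replicate 2. For 3 minus 0.3 ppb it was 5 without 3 ppb replicate 1 or 0.3 ppb replicate 3, 6 without 3 ppb replicate 2 or 3, 8 without 0.3 ppb replicate 2 and 9 without 0.3 ppb replicate 4. For 30 minus 0.3 ppb it was 2 without 30 ppb replicate 4, 4 without 0 ppb replicate 1, 11 without 0.3 ppb replicate 3, 12 without 30 ppb replicate 3 and 13 without 0.3 ppb replicate 2. For 30 minus 3 ppb it was 2 without 3 ppb replicate 1 or 30 ppb replicate 2, 4 without 0 ppb replicate 1 or 3 ppb replicate 4, 11 without 3 ppb replicate 3 and 13 without 30 ppb replicate 3.

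Mean local background was lower at each higher dose in all 4 replicate numbers, from 41.0 ± 1.96 (SD, n = 4) at 0 ppb to 33.6 ± 0.83 (SD, n = 3) at 30 ppb. An exact permutation test of its trend over 82944 orders within replicate numbers gave a two-sided p of 2.41e-05, the smallest the orders can give (adjusted 0.00012 over 5 array measures). The same exact test gave 2.41e-05 for the scaled signal of hsa-miR-4687-3p, picked out of 279 miRNAs after its values were seen. Over 9 miRNAs with both a zebrafish-named and a human-named probe tested, log2 differences agreed in sign for 6 at 0.3 ppb, 5 at 3 ppb and 7 at 30 ppb.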
